A study of Nicotiana tabacum with 32 samples.

How the data were processed

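The samples were suspension cultures of Nicotiana tabacum cv. Xanthi, wild type or silenced for SIPK by RNA interference, kept in MS medium in the dark at 25 C. Per the labels, cells received fresh medium 3 days before treatment, the volumes of each genotype were pooled and divided into 3 volumes of 10 ml, and cells of the abiotic set were incubated with xanthine for 30 min before xanthine oxidase was added. Controls were taken at 0 h. Total RNA of the query and of the reference was labelled with Cy3 and Cy5 and the replicates were paired at random on 3 slides per group.

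One deposited table held 32448 spots by 32 arrays. The deposited values were read as log2 ratios of the 2 channels of each array; the log base, the normalization and which channel was on top are not given in the sources used here, and base 2 and a normalization within each array were assumed. Values were signed and centred near 0, with array medians from -0.066 to 0.070, in order of array -0.033, -0.026 and -0.045 for the biotic control, -0.028, -0.008 and -0.014 for harpin at 4 h, 0.012, 0.010 and 0.013 at 8 h, 0.013, 0.014 and 0.000 for megaspermin at 4 h, -0.052, -0.011 and -0.066 at 8 h, -0.018, 0.000 and -0.033 for the abiotic control, -0.014, 0.008 and -0.028 for xanthine oxidase at 4 h, -0.024, -0.029 and -0.011 at 8 h, 0.070, 0.029 and 0.029 for wild-type harpin and 0.043, 0.014 and -0.043 for wild-type megaspermin. The 2 dye-exchanged arrays had medians of -0.061 (abiotic control) and 0.000 (wild-type harpin). They correlated positively with their standard arrays, so their signs had already been turned. Values were present for 8258 to 21105 spots per array (25.5% to 65.0%) and for 5130 to 10935 clones. Correlations between replicate arrays ran from 0.653 to 0.915 (median 0.810). Among 496 pairs of arrays, 0 held identical values.

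Spots at fixed offsets from each other in the layout were taken as duplicates of 1 clone. The deposited name table paired 905 clones, all 905 as the layout predicts, and the pairing was extended to clones without a name, a step beyond the plan, which covered clones paired by a table. The median correlation of paired spots over arrays was 0.873 for named and 0.697 for other clones, against -0.023 for mismatched spots (8938 clones with enough arrays). This gave 15360 clones, whose 2 spots were averaged; 1728 spots without a partner were left out. Names were potato gene symbols of the deposited name table, which is dated. A single symbol was held by 815 clones (1630 spots, 430 symbols, 339 of them numbered loci), several symbols by 90 clones (180 spots), which were not named, and none by 14455 clones (30638 spots). Potato clones read tobacco transcripts, so a clone can also bind relatives of the named gene.

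Log2 ratios were fitted in R 4.3.3 with limma 3.58.1, as 1 model with a mean for each of 10 groups over the 30 arrays of the standard dye orientation, followed by empirical Bayes moderation (8.02 prior degrees of freedom). A clone was tested in a contrast when at least 2 of the 3 arrays of each group had a value, and p-values were adjusted by Benjamini and Hochberg within each contrast, with a threshold of 0.05. Contrasts were each group mean, the mean of the 8 genotype groups, the difference between the 2 elicitors in wild-type cells, the change of the genotype effect from the control of the same set, and the difference between the 2 controls. Standard errors are those of the moderated model. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used to read tables and draw figures.

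Lists of at least 3 tested clones were tested with camera (preset correlation 0.01), also with an estimated correlation over the 3114 clones with a value on all 30 arrays, and with fry. The lists were redox, defence, carbon metabolism, amino acid (methionine-cycle and one-carbon enzymes included), membrane transport, kinase and calcium, cell cycle, hormone, flavonoid, photosynthesis and storage organ. Lists of name patterns written earlier matched almost nothing, since the table held symbols and no gene descriptions, so these lists of symbols were written after the names but before any value of a gene was seen. Clones called up or down by an elicitor in wild-type cells were followed in the genotype arrays: the median of each array was compared between 3 treated and 3 control arrays by exact permutation, and the clones were tested as a set with camera on the change, with p-values adjusted over the 8 sets (over 16 for the clones followed in other treatments and over 4 for those with a 2-fold change). As wild-type RNA can be shared between arrays, 20 simulations of responses with nothing else in common gave the values that sharing alone produces. Their noise was that between replicate arrays.

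Genes were named by rule: in each contrast, among clones with 1 symbol past the threshold and with 1 sign on every measured array (for a difference, every treated array beyond the mean of the controls), those with the largest absolute log2 ratio, 1 clone per symbol. The rule took 12 up and 12 down for the elicitor responses and the common genotype effect, and 6 up and 6 down for the others, together with up to 4 clones of smallest p from each list described. Symbols stood in for the annotation text that the rule had named. Groups, contrasts, tests, thresholds, the naming rule and the alternatives of the closing section were fixed before the data were examined, except where the text says otherwise.

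The fit was tested on simulated data of normal noise with the residual spread of each clone and 200 changed clones. It found 97% of 2-fold and 33% of 1.41-fold changes in the biotic control (2 false among 132 calls), 67% and 6% in the change with harpin at 4 h (6 false among 79), 79% and 10% in the change with xanthine oxidase at 4 h (5 false among 94) and 72% and 15% in the difference between elicitors (2 false among 89), with 0 calls of the wrong sign. Most of the 1.41-fold changes were thus missed with 3 arrays per group and 200 changed clones. Where more clones change, the adjusted threshold is less strict: the clones called higher in the biotic control had a median log2 ratio of 0.68 and those called lower one of -0.63. Alternatives were arrays centred or scaled, a value on all arrays, the groups of a contrast alone, a replicate block, array weights, spots fitted separately, the exchanged arrays with a dye term, a 2-fold threshold for responding clones, and leaving out each replicate. Counts of clones that passed used the 2 exchanged arrays only with the dye term, and counts of signs kept with the dyes exchanged used them too. Channel intensities and background were not used here.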

Results

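Suspension cells of tobacco (Nicotiana tabacum cv. Xanthi), either wild type or silenced by RNA interference for SIPK, a salicylic acid-induced mitogen-activated protein kinase, were compared on 2-colour arrays. The series held 32 arrays. On 24 of them SIPK-silenced cells were set against wild-type cells in 8 conditions of 3 arrays each: an untreated control, harpin at 4 h and 8 h and megaspermin at 4 h and 8 h (biotic set), and a control and xanthine oxidase at 4 h and 8 h after preincubation with xanthine (abiotic set). Another 6 arrays set wild-type cells treated for 4 h with harpin or megaspermin against untreated wild-type cells, and 2 single arrays repeated a comparison with the dyes exchanged. Harpin is a protein elicitor of Pseudomonas syringae, megaspermin an elicitor of Phytophthora megasperma, and xanthine oxidase produces superoxide from xanthine. The labels give that origin of megaspermin on the genotype arrays but name P. syringae on the wild-type megaspermin arrays, so that the 2 sets received the same elicitor was assumed from its name. Cells of each genotype were pooled and divided into volumes before treatment, so the p-values below measure the spread between volumes of 1 pooled culture and not between independent cultures. All controls were taken at 0 h, and no untreated cells at 4 h or 8 h were on the arrays. Effects of a treatment and of the time since the control therefore cannot be told apart, and a response or change named after a treatment holds both. A positive log2 ratio likely means a higher level in the silenced or treated cells: the labels name these cells as the query and wild-type or untreated cells as the reference, although the sample titles put wild type first and no label states the ratio. Of 15360 clones, 815 carried 1 potato gene symbol and could be named. None of these named clones was recognised as SIPK, so the extent of silencing was not measured here. Values are log2 ratios ± standard error, with n the number of arrays. Where a symbol had several clones, the clone given can differ between comparisons, so such values do not trace 1 clone from condition to condition.

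In wild-type cells at 4 h of harpin, METK1, an S-adenosylmethionine synthetase, rose 3.59-fold (1.84 ± 0.14, n = 3), and all 6 tested METK1 clones rose, by 0.84 to 1.84. The acid invertase PAIN-1 rose 3.49-fold (1.80 ± 0.17, n = 2), the alcohol dehydrogenase ADH1 3.29-fold (1.72 ± 0.25, n = 3) and the NAC transcription factor NAC2 3.28-fold (1.71 ± 0.19, n = 2). The catalase CAT1 fell (-1.04 ± 0.16, n = 3), with its other clones at -0.30 and 0.04. The potassium channel KST1 (-0.99 ± 0.17, n = 3) and the plasma membrane proton pump PHA1 (-0.85 ± 0.10, n = 3) fell too. The polyphenol oxidase PPO fell in a clone (-0.70 ± 0.22, n = 2) that read -0.17 with the dyes exchanged, while its other clone stood at 0.09. Among 16 clones of amino acid, methionine-cycle and one-carbon enzymes, 10 rose, 6 of them METK1, and 2 fell (camera adjusted p = 7.49e-04, adjusted p = 0.451 with an estimated correlation). Methionine synthase, MS, rose in 2 of 5 clones (1.12 ± 0.13, n = 3 for 1 of them). Of 23 clones of carbon metabolism 6 rose and 12 fell (camera adjusted p = 0.793). The alpha-amylase AMYA1 (1.16 ± 0.13, n = 3) and the inorganic pyrophosphatase PPA1 (0.99 ± 0.12, n = 3) rose. Of 10 redox clones 1 rose and 4 fell (camera adjusted p = 0.777), and of 7 defence clones 2 rose and 1 fell (camera adjusted p = 0.793), with the WRKY factor STWRKY8 at 0.57 ± 0.16 (n = 3). Both clones of calcium-dependent and SNF1-related kinases rose (CDPK2 0.77 ± 0.13, n = 3), and the 2 cell cycle clones fell, the D-type cyclin CYCD3.3 by -0.72 ± 0.19 (n = 2). One of 3 flavonoid clones, the flavonol synthase FLS, fell (-0.58 ± 0.20, n = 3). The single clone of the storage organ list, the granule-bound starch synthase GBSS, fell by 0.43, and neither of the 2 clones of the photosystem II subunit PSBR passed. Clones named by a locus number ran from 2.47 ± 0.32 (n = 2) for LOC102577514 to -2.31 ± 0.21 (n = 3) for LOC102590282. With unnamed clones included, the range was 4.39 to -3.98, and 3548 of 6637 tested clones passed an adjusted p of 0.05 (limma), 1784 higher and 1764 lower. Without replicate 2 of the harpin arrays the count was 2198 of 4721 tested clones.

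In wild-type cells at 4 h of megaspermin, ADH1 (1.69 ± 0.25, n = 3), PPA1 (1.41 ± 0.12, n = 3), the auxin response protein IAA2 (1.24 ± 0.17, n = 3), METK1 (1.0 ± 0.15, n = 3) and STWRKY8 (0.96 ± 0.16, n = 3) rose. All 3 CAT1 clones rose, 1 of them by 0.73 ± 0.12 (n = 3). MS fell (-1.15 ± 0.16, n = 3), with all 5 of its clones lower by -0.44 to -1.15. KST1 (-1.35 ± 0.21, n = 2), the phosphoglycerate mutase PGAM (-0.88 ± 0.12, n = 3), the proton pump PHA2 (-0.79 ± 0.12, n = 3) and FLS (-0.80 ± 0.20, n = 3) fell. Of 11 redox clones 4 rose and 1 fell, of 7 defence clones 3 rose, of 22 carbon metabolism clones 5 rose and 8 fell, and of 7 membrane transport clones 1 rose and 5 fell (camera adjusted p = 0.605 for each of the 4 lists). Among the defence clones were PPO (0.57 ± 0.20, n = 3) and the pathogenesis-related protein PR1B (0.51 ± 0.18, n = 2). The amino acid clones went both ways, 7 of 18 up and 5 down (camera adjusted p = 0.957). Clones with a locus number reached 2.96 ± 0.31 (LOC102599567, n = 3) and -2.77 ± 0.17 (LOC102590882, n = 2). Of 7078 tested clones 3259 passed, 1647 higher and 1612 lower. Without replicate 2 of the megaspermin arrays 2112 of 5736 tested clones passed.

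MS was higher with harpin than with megaspermin in all 5 of its clones. One MS clone stood at 1.12 with harpin and -0.52 with megaspermin, a difference of 1.64 ± 0.19 (n = 6), while 3 of the 5 did not pass with harpin alone. METK1 was higher with harpin than with megaspermin (1.11 ± 0.19, n = 6), as were the transketolase TK (0.98 ± 0.18, n = 6), AMYA1 (0.85 ± 0.18, n = 6) and PHA2 (1.18 ± 0.24, n = 6). CAT1 was lower with harpin in 2 clones (-1.41 ± 0.22 and -1.02 ± 0.18, n = 6), and so were the glyceraldehyde-3-phosphate dehydrogenase GAPDH (-0.97 ± 0.21, n = 6) and PPO (-0.95). Of 16 amino acid clones 9 were higher with harpin and 0 lower (camera adjusted p = 1.92e-08; adjusted p = 0.0732 with an estimated correlation). The difference was tested on 6032 clones, of which 836 passed, 418 higher with harpin and 418 lower. The count was 313 with arrays scaled to a common spread, 197 with the 2 groups fitted alone and 527 without replicate 2 of the harpin arrays (4573 clones tested).

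Most of the clones called with both elicitors moved the same way. Of 2246 clones called in both responses, 2179 had the same direction, 1026 up against 408 expected from the 2 counts and 1153 down against 421, and 67 had opposite directions. The log2 ratios of the 2 responses had a correlation of 0.776. Simulated responses that shared nothing but their control RNA had a correlation of 0.502 and a covariance of 0.0125, against 0.398 measured. ADH1, METK1, PPA1, IAA2, STWRKY8 and CDPK2 were among the clones that rose with each elicitor. The time since the 0 h control was common to both responses, so part of the shared direction may come from it.

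Averaged over the 8 conditions, ADH1 was 5.55-fold higher in SIPK-silenced than in wild-type cells (2.47 ± 0.087, n = 24), and the ethylene receptor ERS 4.13-fold higher (2.05 ± 0.10, n = 24). PPO (1.11 ± 0.072, n = 24), PHA2 (1.10 ± 0.060, n = 24), the acireductone dioxygenase ARD (0.98 ± 0.048, n = 24) and STWRKY8 (0.87 ± 0.058, n = 24) were higher too. CAT1 was 2.68-fold lower (-1.42 ± 0.044, n = 24), in all 3 of its clones, and PPA1 (-0.62 ± 0.043, n = 24) and PGAM (-0.51 ± 0.041, n = 24) were lower. Of 20 amino acid clones 13 were higher and 2 lower (camera adjusted p = 0.0162; adjusted p = 0.216 with an estimated correlation), among them all 5 clones of MS. For 7 defence clones the counts were 4 higher and 0 lower, for 8 membrane transport clones 5 and 0, and for 9 redox clones 2 and 5 (camera adjusted p = 0.0709 for each of the 3 lists). Among 23 carbon metabolism clones 12 were higher and 6 lower (camera adjusted p = 0.293). DD (1.05 ± 0.066, n = 24) and the locus LOC102577542 (3.14 ± 0.11, n = 24) were higher and LOC102585195 lower (-2.66 ± 0.11, n = 24). SS16 was higher in 2 clones (1.94 ± 0.074 for 1 of them, n = 24) and lower in 1 (-0.28 ± 0.040, n = 24). Of 6602 tested clones 4776 passed, 2333 higher and 2443 lower in silenced cells. With the dye-exchanged arrays and a dye term in the model, a setting chosen after the data were seen, 2641 passed. The dye bias estimates of the 2 exchanged comparisons had a correlation of 0.111 over 5481 clones. Each estimate holds the noise of a single exchanged array, so whether the bias of 1 condition holds in another was not settled.

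**Figure D1:**
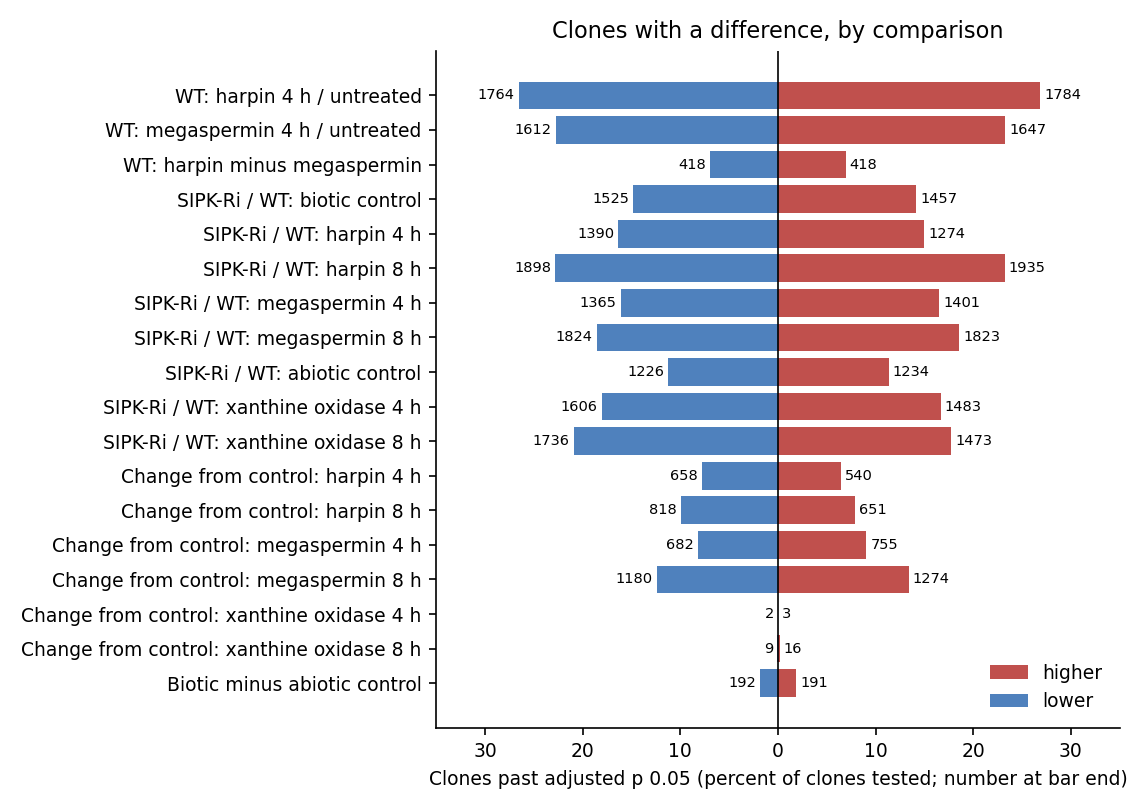
Percent of tested clones higher or lower at an adjusted p of 0.05 in each comparison; each bar is 1 comparison and direction, and the number at its end is the count of clones. The change with xanthine oxidase had 5 clones at 4 h and 25 at 8 h.

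In the biotic control, before any elicitor, ADH1 was 11.1-fold higher in silenced cells (3.47 ± 0.25, n = 3) and ERS 6.15-fold higher (2.62 ± 0.28, n = 3). PPO was higher in 2 clones (2.45 ± 0.20 and 2.17 ± 0.18, n = 3), as were GBSS (1.64 ± 0.14, n = 3), the hydroperoxide lyase HPL (1.19 ± 0.20, n = 3), ARD (1.15 ± 0.14, n = 3) and PAIN-1 (0.98 ± 0.14, n = 3). The Ran GTPase-activating protein RANGAP2 (-0.72 ± 0.14, n = 3) and PPA1 (-0.66 ± 0.12, n = 3) were lower, and 3 of 9 METK1 clones were lower (-0.46 ± 0.12, n = 3 for 1 of them). Of 11 defence clones 5 were higher and 0 lower (camera adjusted p = 0.00915; adjusted p = 0.302 with an estimated correlation), and of 25 carbon metabolism clones 10 were higher and 3 lower (camera adjusted p = 0.00915; adjusted p = 0.628 with an estimated correlation). Amino acid clones had 2 higher and 3 lower of 22 (camera adjusted p = 0.99). Of 10276 tested clones 2982 passed, 1457 higher and 1525 lower. The count was 4683 with array weights, 1949 with a dye term and 1972 without replicate 1.

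In the abiotic control, CAT1 was 3.83-fold lower in silenced cells (-1.94 ± 0.12, n = 3), and all 9 METK1 clones were higher, 1 of them by 1.11 ± 0.14 (n = 3). PHA2 (1.09 ± 0.12, n = 3), ERS (1.49 ± 0.28, n = 3), PPO (1.42 ± 0.20, n = 3), STWRKY8 (1.28 ± 0.16, n = 3), ADH1 (1.24 ± 0.25, n = 3) and MS (1.08 ± 0.13, n = 3) were higher, while RANGAP2 (-0.82 ± 0.14, n = 3) and PGAM (-0.63) were lower. On the single array with the dyes exchanged STWRKY8 read 0.57, and its other clone -0.22 against 0.42 on the standard arrays. On that array ERS read 1.40, PPO 1.01, ADH1 1.20 and MS 1.20. Of 22 amino acid clones 14 were higher, most of them METK1, and 0 lower (camera adjusted p = 8.55e-07, adjusted p = 0.0597 with an estimated correlation). Of 12 defence clones 5 were higher and 0 lower (camera adjusted p = 0.00231, adjusted p = 0.0597 with an estimated correlation). The 3 membrane transport clones that were higher, of 9, were all PHA2 (camera adjusted p = 0.0116; adjusted p = 0.119 with an estimated correlation). Of 10868 tested clones 2460 passed, 1234 higher and 1226 lower. The count was 3879 with arrays scaled, 3991 with array weights and 1632 without replicate 2.

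Between the 2 controls the genotype effect differed for ADH1, CAT1 and METK1. ADH1 stood 4.67-fold further up in the biotic control (difference 2.22 ± 0.35, n = 6), and GBSS (1.32 ± 0.20, n = 6) and PPO (1.03 ± 0.29, n = 6) also stood higher there. SS16 stood higher in 2 clones (1.95 ± 0.29 for 1 of them, n = 6) and lower in 1 (-0.65 ± 0.16, n = 6). CAT1, lower in silenced cells of the abiotic control, stood higher in the biotic control in 2 of 3 clones (1.61 ± 0.18 for 1 of them, n = 6). METK1 stood lower in the biotic control in 8 of 9 clones (-1.71 ± 0.29, n = 6), and STWRKY8 (-1.14 ± 0.23, n = 6) and PHA2 (-0.90 ± 0.24, n = 6) stood lower. Of 22 amino acid clones 9 stood lower, most of them METK1, and 0 higher (camera adjusted p = 2.11e-12, adjusted p = 0.0468 with an estimated correlation). Of 11 redox clones 2 stood higher, both CAT1 (camera adjusted p = 0.0262, adjusted p = 0.0468 with an estimated correlation). Carbon metabolism had 3 of 25 clones higher (camera adjusted p = 0.00208; adjusted p = 0.39 with an estimated correlation), and membrane transport 2 of 9 lower (camera adjusted p = 0.00289; adjusted p = 0.272 with an estimated correlation). Of 10223 clones 383 passed, 191 higher and 192 lower in the biotic control. The count was 950 with arrays scaled, 741 with the groups alone, 1513 with array weights and 182 without replicate 1 of the biotic control. Among 1656 clones called in both controls, 1622 had the same direction.

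With harpin at 4 h, ERS (2.53 ± 0.28, n = 3), ADH1 (2.22 ± 0.25, n = 3), PPO (1.56 ± 0.20, n = 3) and the serine hydroxymethyltransferase SHMT (1.28 ± 0.17, n = 3) were higher in silenced than in wild-type cells, and STUGE51 (-1.77 ± 0.16, n = 3), CAT1 (-1.31 ± 0.12, n = 3) and AMYA1 (-0.92 ± 0.13, n = 3) were lower. At 8 h ADH1 was 11.2-fold higher (3.49 ± 0.25, n = 3), ERS 10.1-fold (3.33 ± 0.28, n = 3), MS 1.24 ± 0.16 (n = 3) and STWRKY8 0.98 ± 0.16 (n = 3). At this time 2 CAT1 clones were lower (-0.88 ± 0.16, n = 3 for 1 of them) and the remaining CAT1 clone was higher (0.46 ± 0.19, n = 3). Of 9 defence clones 6 were higher and 0 lower at 4 h (camera adjusted p = 0.0176; adjusted p = 0.648 with an estimated correlation) and again 6 and 0 of 9 at 8 h (camera adjusted p = 0.416). At 4 h 2664 of 8503 tested clones passed (1274 higher, 1390 lower), and at 8 h 3833 of 8324 (1935 higher, 1898 lower). With a dye term 1633 passed at 4 h.

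Against the biotic control, the genotype effect at 4 h of harpin was lower for ADH1 (-1.24 ± 0.35, n = 6), GBSS (-1.19 ± 0.20, n = 6), PPO (-1.07 ± 0.26, n = 6), CAT1 (-0.98 ± 0.18, n = 6), PAIN-1 (-0.94 ± 0.20, n = 6) and the vacuolar processing enzyme VPE2 (-0.71 ± 0.19, n = 6), and higher for STWRKY8 (0.87 ± 0.22, n = 6). At 8 h PPO stood below the control (-1.81 ± 0.29, n = 6), and MS (0.95 ± 0.22, n = 6) and STWRKY8 (0.86) stood above it. None of the gene lists passed with camera at either time (with fry, membrane transport at 4 h had an adjusted p = 0.0179, downward, with 0 of 8 clones past the threshold). Carbon metabolism had 0 of 25 clones up and 5 down at 4 h (camera adjusted p = 0.214), and amino acid enzymes 3 of 21 up and 0 down at 8 h (camera adjusted p = 0.90). The change passed for 1198 of 8429 clones at 4 h (540 up, 658 down) and for 1469 of 8244 at 8 h (651 up, 818 down). With array weights the counts were 1967 and 2663.

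With megaspermin at 4 h, CAT1 was 4.25-fold lower in silenced cells (-2.09 ± 0.16, n = 3) and all 3 of its clones were lower. The auxin response protein IAA3 (-1.55 ± 0.16, n = 3) was lower as well, and ADH1 was 3.50-fold higher (1.81 ± 0.25, n = 3), ahead of ERS (1.64 ± 0.28, n = 3), PHA2 (1.42 ± 0.12, n = 3), TK (1.21 ± 0.13, n = 3) and all 5 clones of MS. At 8 h ADH1 (2.15 ± 0.25, n = 3), MS (1.59 ± 0.16, n = 3), PHA2 (1.55 ± 0.17, n = 3), STWRKY8 (1.38 ± 0.16, n = 3), the pyruvate kinase PK (1.35 ± 0.14, n = 3), PHA1 (1.22 ± 0.10, n = 3) and the uncoupling protein UCP (1.06 ± 0.15, n = 3) were higher, and CAT1 (-1.32 ± 0.12, n = 3) and IAA2 (-1.15 ± 0.17, n = 3) were lower. At 4 h 9 of 20 amino acid clones were higher and 1 lower (camera adjusted p = 0.0043; adjusted p = 0.26 with an estimated correlation), and 3 of 11 redox clones were lower, all CAT1 (camera adjusted p = 0.0145; adjusted p = 0.101 with an estimated correlation). Membrane transport had 3 of 8 clones higher at 4 h, all PHA2 (camera adjusted p = 0.0145; adjusted p = 0.26 with an estimated correlation), and 5 of 9 at 8 h (camera adjusted p = 4.69e-04; adjusted p = 0.106 with an estimated correlation). At 4 h 2766 of 8476 clones passed (1401 higher, 1365 lower) and at 8 h 3647 of 9819 (1823 higher, 1824 lower). A dye term left 1822 at 4 h, and leaving out replicate 2 left 2378 at 8 h, where centring the arrays gave 2059 higher and 1520 lower.

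Against the biotic control, the genotype effect with megaspermin was lower for PPO, by -1.57 ± 0.29 at 4 h and -2.90 ± 0.29 at 8 h (n = 6). IAA3 (-1.85 ± 0.23, n = 6), CAT1 (-1.80 ± 0.22, n = 6), GBSS (-1.69 ± 0.22, n = 5) and ADH1 (-1.66 ± 0.35, n = 6) stood below the control at 4 h, and PHA2 (1.14 ± 0.17, n = 6) and all 5 MS clones (0.90 ± 0.23 for 1 of them, n = 6) above it. At 8 h ERS (-1.38 ± 0.40, n = 6), IAA2 (-1.07 ± 0.24, n = 6) and CAT1 (-0.99 ± 0.18, n = 6) stood below the control, and MS (1.39 ± 0.23, n = 6), STWRKY8 (1.24 ± 0.23, n = 6), the sucrose transporter SUT2 (1.01 ± 0.26, n = 4), PGAM (0.96 ± 0.17, n = 6) and PHA1 (0.92 ± 0.14, n = 6) above it. At 4 h 9 of 20 amino acid clones rose and 0 fell (camera adjusted p = 0.00843; adjusted p = 0.258 with an estimated correlation), 2 of 10 redox clones fell (camera adjusted p = 0.0128; adjusted p = 0.0543 with an estimated correlation). Membrane transport had 1 of 8 clones up (camera adjusted p = 0.0486; adjusted p = 0.494 with an estimated correlation), and 1 of 4 hormone clones, IAA3, fell (camera adjusted p = 0.0486; adjusted p = 0.0543 with an estimated correlation). At 8 h 4 of 9 membrane transport clones rose (camera adjusted p = 0.013; adjusted p = 0.128 with an estimated correlation), 3 of 4 hormone clones fell, and of 11 defence clones 2 rose and 4 fell (camera adjusted p = 0.073 for both lists). The change passed for 1437 of 8338 clones at 4 h (755 up, 682 down) and for 2454 of 9496 at 8 h (1274 up, 1180 down). Of the clones called at both times, 864 of 881 had the same direction. Both changes subtract the same control arrays, which alone gave a correlation of 0.501 and a covariance of 0.0257 in simulations, against 0.657 and 0.218 measured. With array weights 2663 passed at 4 h, and with arrays centred the majority at 4 h turned, to 628 up and 752 down. Harpin and megaspermin shared 486 called clones at 4 h, 468 with the same direction and 18 opposite (correlation 0.541, against 0.503 in simulations of the shared control; covariance 0.138 against 0.0255). At 8 h they shared 750, 608 with the same direction and 142 opposite (correlation 0.442 against 0.499; covariance 0.148 against 0.0255).

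**Figure D2:**
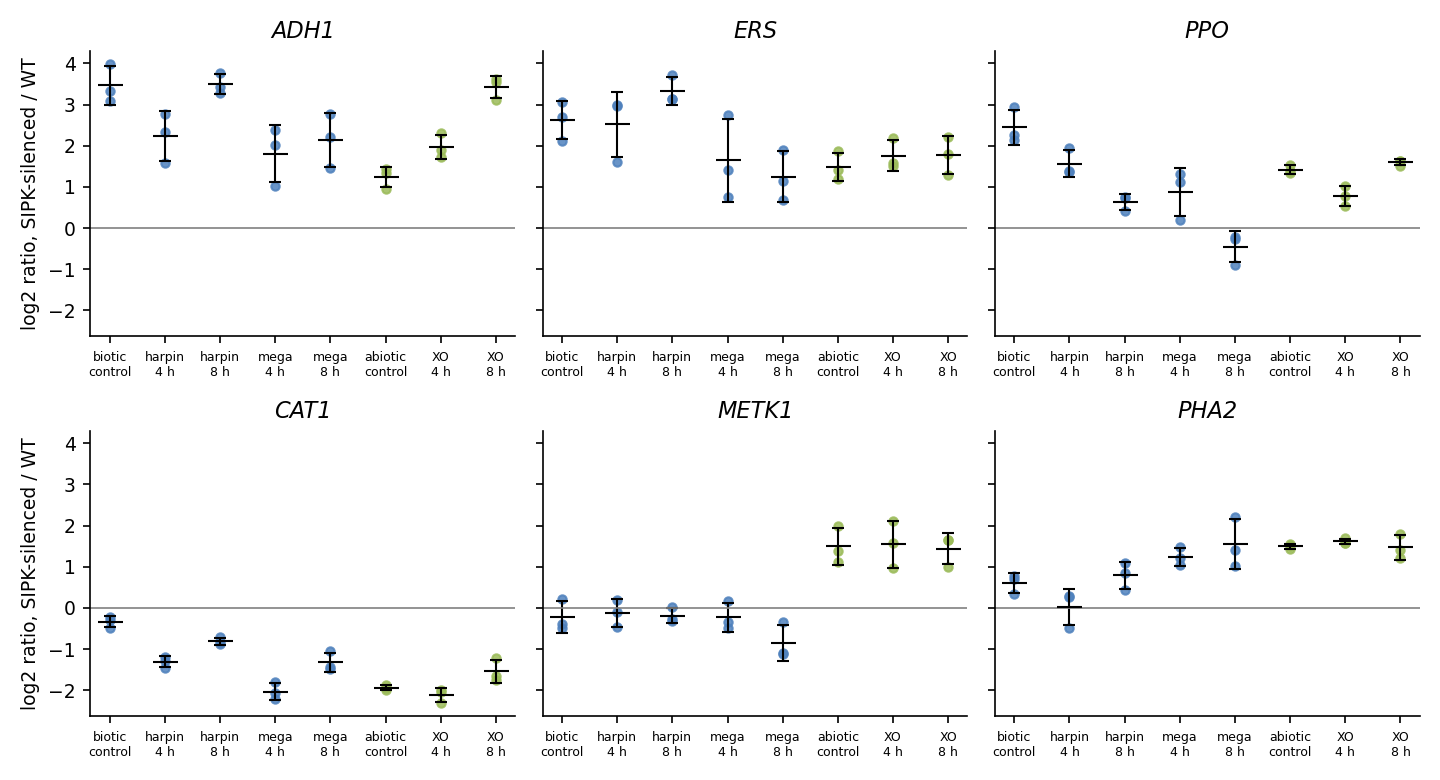
Log2 ratio of SIPK-silenced over wild-type cells for 1 clone each of ADH1, ERS, PPO, CAT1, METK1 and PHA2 in the 8 conditions; points are arrays, bars the mean ± SD of 3 arrays. ADH1 had a model mean of 3.47 in the biotic and 1.24 in the abiotic control.

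The clones that megaspermin changed in wild-type cells were taken as 2 groups and followed in silenced cells. Among those lowered by megaspermin, the median genotype effect rose from -0.19 ± 0.015 in the control to 0.12 ± 0.081 at 4 h (mean ± SD of 3 arrays), and 444 of these clones passed the test of the change upward and 45 downward. Over 1568 clones the median change was 0.33 (camera adjusted p = 1.78e-17). Among those raised by megaspermin the genotype effect went from -0.053 ± 0.018 to -0.20 ± 0.099, with 288 passing downward and 63 upward, and the median change over 1597 clones was -0.16 (camera adjusted p = 4.92e-08). In simulations in which only the wild-type RNA was shared between arrays the medians were 0.040 and -0.047. At 8 h the median change was 0.43 among the clones lowered at 4 h (camera adjusted p = 8.4e-21) and -0.27 among those raised (camera adjusted p = 8.25e-06). The megaspermin response and the change of the genotype effect at 4 h shared 840 called clones, 732 of them with opposite directions against 300 expected, and their correlation was -0.448 against -0.156 in the simulations. The exact permutation test of 3 against 3 arrays gave p = 0.1 for each of these 4 medians, the smallest it allows.

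The clones that harpin changed were followed in the same way. Clones raised by harpin in wild-type cells had a median change of -0.043 at 4 h (1731 clones; camera adjusted p = 0.233), and clones lowered by harpin one of 0.10 (1702 clones; camera adjusted p = 0.00634), where the simulations gave -0.046 and 0.034. The exact permutation test compared the medians of arrays, which rose for the raised clones, from 0.017 ± 0.015 in the control to 0.037 ± 0.088 (mean ± SD of 3 arrays). This is opposite in sign to their median change, so the direction was not settled. For the lowered clones the array medians went from -0.195 ± 0.019 to -0.103 ± 0.083. The exact permutation p was 0.7 for the raised and 0.1 for the lowered clones. At 8 h the changes had the sign of the harpin response, 0.14 for the raised (camera adjusted p = 8.25e-06) and -0.23 for the lowered clones (camera adjusted p = 1.17e-09). In comparisons added after the data were seen, these clones changed in the same direction with xanthine oxidase at 8 h. The raised clones changed by 0.10 (camera adjusted p = 7.1e-10) and the lowered by -0.11 (camera adjusted p = 1.35e-05). With megaspermin at 8 h they went the other way, at -0.18 and 0.31 (camera adjusted p = 0.0187 and 7.1e-10). Clones raised or lowered by megaspermin changed by 0.092 and -0.16 at 8 h of harpin (camera adjusted p = 5.11e-04 and 9.66e-06). The exact permutation test of 3 against 3 arrays gave p = 0.1, the smallest it allows, for each of these changes at 8 h. The camera p-values compare clones and not arrays. Among clones with at least a 2-fold rise with harpin the median change at 4 h was -0.15 (345 clones; camera adjusted p = 0.00396), where simulations with that threshold ran from -0.108 to -0.0328. Without replicate 2 of the harpin arrays on silenced cells the median of the raised clones was -0.099, and without replicate 1 that of the lowered clones was 0.053.

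**Figure D3:**
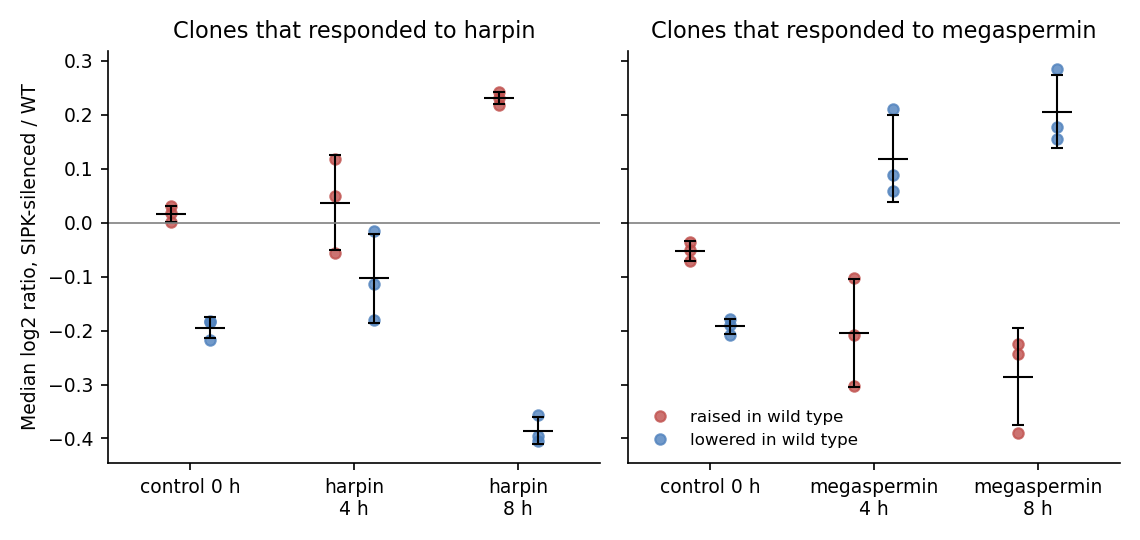
Median log2 ratio of SIPK-silenced over wild-type cells among clones raised or lowered by harpin or megaspermin in wild-type cells, in the control (0 h), at 4 h and at 8 h; points are arrays, bars the mean ± SD of 3 arrays. With megaspermin the lowered clones went from -0.19 to 0.12 at 4 h.

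With xanthine oxidase, CAT1 was 5.56-fold lower in silenced cells at 4 h (-2.47 ± 0.16, n = 3) and lower at 8 h (-1.59), while ADH1 was higher at 4 h (1.97 ± 0.25, n = 3) and 10.7-fold higher at 8 h (3.42 ± 0.25, n = 3). PHA2 was higher at both times (1.61 ± 0.17, n = 3, and 1.47), as were METK1 (1.36 ± 0.14 and 1.42 ± 0.15, n = 3; 8 and 9 of 9 clones), STWRKY8 (1.11 and 1.09) and ERS (1.75 and 1.77). PPA1 (-1.04 ± 0.12, n = 3, and -0.72), PGAM (-0.85 and -1.04) and RANGAP2 (-0.98 and -0.67) were lower. Amino acid enzymes had 14 of 21 clones higher and 0 lower at 4 h (camera adjusted p = 9.54e-07, adjusted p = 0.0852 with an estimated correlation). At 8 h 15 of 20 were higher and 2 lower (camera adjusted p = 9.45e-07, adjusted p = 0.0696 with an estimated correlation). Most of the higher amino acid clones were METK1. Defence clones had 4 of 8 higher at 4 h (camera adjusted p = 0.171) and 6 of 9 at 8 h (camera adjusted p = 0.00432; adjusted p = 0.0696 with an estimated correlation), and 0 lower at either time. At 4 h 3089 of 8890 clones passed (1483 higher, 1606 lower) and at 8 h 3209 of 8301 (1473 higher, 1736 lower). With a dye term the counts were 1910 and 2054.

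Few clones changed their genotype effect from the abiotic control. At 8 h ADH1 stood 4.52-fold further up (2.18 ± 0.35, n = 6), 1 of 3 SS16 clones stood up by 1.40 ± 0.29 (n = 6; not past the threshold with arrays scaled) and LOC102600029 by 1.92 ± 0.20 (n = 6). The only named clone past the threshold at 4 h was LOC102577893 (0.99 ± 0.19, n = 6). In limma 5 of 8884 clones passed at 4 h (3 up, 2 down; 692 at an unadjusted p under 0.05) and 25 of 8285 at 8 h (16 up, 9 down; 710 unadjusted), and none of the gene lists passed with camera (with fry, the defence list at 4 h had an adjusted p = 0.045, downward, with 0 of 8 clones past the threshold). The calls of the abiotic control were shared in turn: of 1895 clones called in the control and at 4 h 1893 had the same direction, and at 8 h 1961 of 1962. With arrays scaled 126 and 121 clones passed and with array weights 511 and 411; with a replicate block 0 passed at 4 h and 20 at 8 h. Leaving out single arrays gave 0 to 4 clones at 4 h and 7 to 80 at 8 h, with 7 without replicate 1 of the abiotic control and 80 without replicate 2 of xanthine oxidase at 8 h.

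With the dyes exchanged, the harpin response of wild-type cells had a correlation of 0.900 with the standard arrays, and 2970 of 3071 called clones (96.7%) kept their sign. For the abiotic control the correlation was 0.717 and 2172 of 2432 clones (89.3%) kept their sign. The median of the exchanged over the standard ratio of called clones was 1.09 for wild-type harpin and 0.641 for the abiotic control. Of the called clones with a symbol other than a locus number, 64 of 67 kept their sign for wild-type harpin and 51 of 54 for the abiotic control. The dye bias, the mean of the standard and the exchanged ratios read as 1 dye over the other, had an SD over clones of 0.190 and 0.177, array noise included.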

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

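The tests of the error, of the clones tested and of the spread of ratios for xanthine oxidase, and those of shared wild-type RNA, were chosen after the results were seen. Most results in this part stand out because the same contrast differed between groups by a test of the difference itself. The counts with xanthine oxidase and with the elicitors were set side by side, and these changes were not tested against each other.

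The genotype effect of few clones changed with xanthine oxidase, 5 at 4 h and 25 at 8 h, against 1198, 1469, 1437 and 2454 with harpin at 4 h and 8 h and megaspermin at 4 h and 8 h. A larger error of the xanthine oxidase arrays would widen the spread of the change, but among 6602 clones tested in all 6 differences its SD was 0.267 and 0.263 with xanthine oxidase and 0.489 to 0.661 with the elicitors, a ratio of at most 0.546 (error of the arrays of each difference 0.192 and 0.223, against 0.194 to 0.222). Testing fewer clones was not the cause either. Among these clones the counts were 5 and 20 with xanthine oxidase and 1094 to 2312 with the elicitors, a ratio of at least 54.7. Over all tested clones the lowest elicitor count over the highest xanthine oxidase count was 47.9 as deposited. With arrays scaled it was 11.1, and with array weights 3.85. Scaling narrowed the gap without closing it, so compressed ratios on the abiotic control arrays may account for part of it. It may be that xanthine oxidase altered these cells less, a hypothesis that stays open because wild-type cells with and without xanthine oxidase were not compared on the arrays used here and the 2 sets were prepared separately.

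Clones lowered by megaspermin in wild-type cells had a rise of the genotype effect and clones raised had a fall, with median changes of 0.33 and -0.16 at 4 h and 0.43 and -0.27 at 8 h. Wild-type RNA shared between arrays gives changes of this direction without any biology, but 4 of 4 medians lay outside the range of 20 simulations of such sharing. The simulated noise was that between replicate arrays, so a deviation common to all wild-type volumes of a condition was not covered, here or for harpin. For harpin at 8 h the medians, 0.14 and -0.23, had the sign of the response, and 2 of 2 were opposite in sign to the simulations and outside their range, but the same clones also moved that way with xanthine oxidase at 8 h (0.10 and -0.11), so the direction was not particular to harpin. At 4 h of harpin, wild-type RNA shared between arrays could account for the raised clones as a whole, at -0.0427 within a simulated range of -0.0551 to -0.0321 (-0.0987 to -0.00546 on leaving out single arrays, in and out of that range), whereas clones raised at least 2-fold, at -0.154, lay outside -0.108 to -0.0328 and the lowered clones, at 0.10, outside 0.0248 to 0.0448. For the harpin-raised clones as a whole the difference of array medians at 4 h was 0.0207, opposite in sign to -0.0427, so the direction was not settled. A weaker megaspermin response in silenced cells is a candidate explanation of the opposite change with megaspermin. At 4 h of megaspermin the harpin-lowered clones also rose (0.19), while the harpin-raised clones did not pass (-0.028, camera adjusted p = 0.174). A shift in timing stays open, as no array compared wild-type cells at 8 h with their control.

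The counts of clones past the threshold were compared with those of other splits of the arrays or of other sets of array signs. For the common genotype effect 1 of 100 sets of signs, the real one, gave as many clones (4776, highest other 1975). This argues against noise that differs between arrays. A difference that all arrays carry, from the pooled culture of each genotype or from the dyes, keeps its sign and was not tested. All other comparisons allow too few splits for a share under 0.05. The highest other counts among 4 sets of signs each were 696 for harpin (3548 real) and 932 for megaspermin (3259) in wild-type cells, 0 for the biotic control (2982), 20 and 102 for the genotype effect with harpin at 4 h and 8 h (2664 and 3833), 55 and 12 with megaspermin (2766 and 3647), 1 for the abiotic control (2460), and 1 and 8 with xanthine oxidase (3089 and 3209). Among 10 splits each they were 200 for the difference between elicitors (836 real), 0 and 15 for the change with harpin, 1 and 7 with megaspermin, 1 and 1 with xanthine oxidase, and 0 for the difference between controls (383).

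Between elicitors in wild-type cells, CAT1 stood at -0.30 with harpin and 0.73 with megaspermin (difference -1.02 ± 0.18) and in a further clone at -1.04 and 0.37 (-1.41 ± 0.22). MS stood at 1.12 and -0.52 (1.64 ± 0.19) and PHA2 at 0.65 and -0.52 (1.18 ± 0.24). The genotype effect on VPE2 was 0.41 in the biotic control and -0.40 with megaspermin at 4 h (-0.81 ± 0.19) and -0.44 at 8 h (-0.85 ± 0.19). For PGAM it was -0.53 in the biotic control and 0.43 with megaspermin at 8 h (0.96 ± 0.17). METK1 had a clone at -0.41 in the biotic and 0.55 in the abiotic control (-0.96 ± 0.18).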

How the results depend on the processing

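The dye term for conditions other than the abiotic control and wild-type harpin was chosen after the data were seen. Counts of clones not given here stayed within 1.5 times their value in each alternative run, and the cause of each shift was not tested unless stated. Among 572 named clone and comparison pairs, 115 missed the threshold in at least 1 alternative and 2 turned sign: DHAR in the harpin response of wild-type cells (0.28) and CYCD3.2 in the common genotype effect (-0.061), both with the dye term. Missed pairs numbered 8 with centring, 33 with scaling, 34 with the groups alone, 12 with the replicate block, 13 with array weights, 6 of 565 with separate spots, 45 of 413 with the dye term and 0 of 535 with a value on all arrays. Over all alternatives that left out an array, 189 of 3162 missed. Centring shifted the median of no comparison by more than 0.056, but it moved the share of clones called higher, from 52.5% to 45.5% for the change with megaspermin at 4 h, from 50.3% to 46% for wild-type harpin, from 48.9% to 54.3% for the biotic control and from 50.0% to 57.5% for megaspermin at 8 h, so near-even splits of higher and lower depend on it. Channel intensities and background were not used here, so what signal over background limits was not assessed.

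With arrays scaled, 313 clones passed for the difference between elicitors, 3879 for the abiotic control, 950 for the difference between controls, and 126 (41 up, 85 down) and 121 (68 up, 53 down) for the change with xanthine oxidase at 4 h and 8 h. With the groups alone the counts were 197 for the difference between elicitors, 741 for that between controls, and 9 and 4 with xanthine oxidase. Array weights gave 4683 for the biotic and 3991 for the abiotic control, 1967 and 2663 for the change with harpin, 2663 with megaspermin at 4 h, 511 (223 up, 288 down) and 411 (194 up, 217 down) with xanthine oxidase, and 1513 between controls. Separate spots gave 3 with xanthine oxidase at 4 h. The dye term gave 1949 for the biotic control and 2641 for the common effect. For the genotype effect with harpin and megaspermin at 4 h it gave 1633 and 1822. With xanthine oxidase it gave 1910 and 2054 at 4 h and 8 h. These counts rest on a bias that was not measured in the conditions without an exchanged array. The 2 estimates of that bias, noise of single exchanged arrays included, had a correlation of 0.111. Harpin-raised clones with a 2-fold change had a median of -0.154. Of 171 tests of lists, 25 passed with camera. Of the 114 pairs of list and comparison also tested with fry and with an estimated correlation, 69 passed with fry and 2 with an estimated correlation.

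Replicate numbers did not pair arrays across groups: residuals of arrays with 1 number had a median correlation of -0.027 (-0.415 to 0.364), and 9 of 30 arrays matched their own number best. A replicate block gave 0 clones for xanthine oxidase at 4 h in limma (692 at an unadjusted p under 0.05 without the block).

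Leaving out 1 array at a time gave 2198 to 3153 clones for harpin and 2112 to 3119 for megaspermin in wild-type cells, 527 to 798 for their difference, 1972 to 2262 for the biotic control, 2378 to 3167 for megaspermin at 8 h, 1632 to 1819 for the abiotic control, 182 to 290 between controls, and 0 to 4 and 7 to 80 with xanthine oxidase at 4 h and 8 h. The lowest counts came without replicate 2 for wild-type harpin, wild-type megaspermin, their difference (a harpin array), megaspermin at 8 h and the abiotic control, and without replicate 1 of the biotic control for the biotic control and the difference between controls. The median of harpin-raised clones ran from -0.0987 to -0.00546 and that of harpin-lowered clones from 0.0527 to 0.147. The correlation with the exchanged harpin array ran from 0.847 to 0.901. Where a difference between groups was refitted without an array, fewer arrays entered the test. Leaving out an array also lowered the number of clones tested, for wild-type harpin without replicate 2 from 6637 to 4721, so these counts fell partly for that reason.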

Other observations

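The genes in the next 2 paragraphs were singled out after their values were seen; of the tests on LOC102587499, that of single spots was chosen after the result was seen.

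In wild-type cells GAPDH, a glycolytic enzyme, was lower with harpin in 7 of 8 clones (-0.32 to -1.14) and with megaspermin in 2 of 8. NDPK1, a nucleoside diphosphate kinase, fell with megaspermin (-0.93), and its genotype effect rose from the biotic control by 0.87 at 4 h of megaspermin. The aquaporin MIP2 was higher in silenced cells of the biotic control (1.29), and this effect was lower by -1.47 and -1.28 with harpin at 4 h and 8 h and by -1.66 with megaspermin at 8 h. For the transcription factor NAC2 the genotype effect was 0.82 in the biotic control and 1.63 at 8 h of harpin, with changes of -0.88 at 4 h and 0.81 at 8 h. In the abiotic control NAC2 read 0.90 on the standard arrays but -0.082 on the single array with the dyes exchanged. Its genotype effect in single conditions may thus hold dye bias.

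The pectin methylesterase PME1 was lower in silenced cells throughout the abiotic set (-0.90 in the control, -1.16 and -1.02 with xanthine oxidase). SHKA, which starts aromatic amino acid synthesis, was higher in silenced cells with megaspermin at 4 h (0.73) and 8 h (0.77). METK1 was higher in 9, 8 and 9 of 9 clones in the control and with xanthine oxidase at 4 h and 8 h. Of 122 symbols with at least 2 clones called in the common genotype effect, 109 had all called clones in 1 direction and 13 in both.

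The 10 clones of LOC102587499 had opposite genotype effects in the abiotic control, 5 higher and 4 lower, from 3.32 to -3.57. Noise of single spots would give either sign on other arrays, but in the 7 other conditions 115 of 126 values of single spots (91.3%) had the sign of their clone in the abiotic control. Members of a gene family on clones of one name would follow 1 course within a direction, and the median correlation over the 8 conditions was 0.906 between clones of 1 direction and -0.881 between directions. Effects of opposite sign that grow and shrink together would give these correlations too, so they do not tell a gene family apart. Several family members may stand under this name, but sequences, which would decide it, were not used here.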
